A study of Drosophila melanogaster with 3 samples.

How the data were processed

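RNA immunoprecipitation followed by sequencing (RIP-seq) was recorded for 3 libraries of Drosophila melanogaster S2R+ cells, a line derived from the hemocyte-like Schneider 2 cells. The labels place all 3 libraries in 1 group, immunoprecipitates of ps (pasilla), and number them as biological replicates 1, 2 and 3. They name ps as the antibody target, and whether the tag or the protein was precipitated is not given in the sources used here. They also name a possible control experiment, which was not used here. No input, mock or untagged library was used here, so every value below is abundance in the immunoprecipitate and not enrichment over a background.

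Each library came as 1 table of normalized read signal per base. Per the text that the authors deposited with each table, this signal was derived from alignments to the dm3 assembly and covers all reads. The tables do not separate the strands. The aligner, its version, the treatment of reads with several alignments and the treatment of duplicate reads are not given in the sources used here. The deposited signal was checked against whole reads. Every value was a whole multiple of the smallest value of its library within a relative tolerance of 1e-06. The signal summed to 50 bases per alignment in each library, and of the isolated blocks of depth 1, between 95.9% and 96.7% were 50 bases long. The unit of the deposited signal is therefore alignments of 50-base reads at each base, scaled to the same total of alignments in every library. The smallest step gave the depth as 17916993 alignments in replicate 1, 14029729 in replicate 2 and 31616295 in replicate 3. Amplified reads without molecular identifiers are not independent molecules, so intervals given here cover counting error only.

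Signal was summed per chromosome and in consecutive bins of 1000 bases, and alignments per bin were taken as the summed depth divided by 50. The main arms were X, 2L, 2R, 3L, 3R and 4. The 8 other sequences were the mitochondrial chromosome M, the unplaced sequences U and the heterochromatic sequences XHet, 2LHet, 2RHet, 3LHet, 3RHet and YHet. The length of a sequence was taken as the last covered base in any library. Shares of a single library carry Wilson 95% confidence intervals. Spearman's rho and Pearson's r of log2(signal + 4e-05) were computed across bins of the main arms with signal in at least 1 library. Bins are not independent replicates, so no p-value was attached to them.

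The groups, tests, alternatives and naming rules were fixed before the data were examined. The test for high-signal bins used log2(signal + 4e-05), centred on each library's median over main-arm bins with signal in all 3 libraries. Bins were tested with limma 3.58.1 in R 4.3.3, with an intercept model and a one-sided moderated test against a 10-fold difference, at a Benjamini-Hochberg adjusted p of 0.05. The pseudocount followed a rule set in advance (the smallest non-zero bin signal, rounded up). Bins at 0 in some library have a large spread on this scale, and the test called no bin. On simulated libraries over 73592 bins, with a replicate spread of 0.5 on the log2 scale, it called 0% of bins raised 80-fold. The alternative named in advance was restricted to bins with signal in all 3 libraries. It called 86.0% of bins raised 20-fold and 100% of those raised 40-fold over 54485 simulated bins. It called 0% of those raised 5-fold, with 1 false call. The simulated libraries all shared 1 spread, which the real ones did not. Among bins with at least 40 alignments in a pair, 1.62% differed more than 2-fold between replicates 1 and 2. The share was 42.4% and 44.1% in the pairs with replicate 3, so recovery at the spread of these libraries is unknown. Regions were named from this alternative because the planned test called no bin, a choice made after both counts were seen.

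Sharp local summits were windows of 100 bases with at least 20 alignments on average. The log2 ratio of a window to its flanks of 400 bases on each side was tested in the same way against a 4-fold difference. On simulated data over 122702 windows, 76.0% of windows raised 16-fold and 100% of those raised 64-fold were called, and 0% of those raised 2-fold. The simulated spread was again 0.5 on the log2 scale, and whether it matches that of these windows was not examined. Where the flanks held fewer than 3 alignments in a library, the ratio is given as a bound against 3 alignments in the 800 flanking bases. A fold change on the log2(signal + pseudocount) scale against a flank at 0 depends on the pseudocount and is no bound, so such values are printed only on the log2 scale, to compare settings.

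Regions were named by rule. Adjacent high-signal bins were merged, and the 20 regions of the main arms with the highest signal in their lowest library were named, with the highest region of every other sequence. Of the summits, the 10 with the largest mean ratio were named. Coordinates are 1-based dm3 positions. The gene table supplied for this work refers to Release 6 of the genome and not to dm3, so no gene names, exons or sequence motifs were assigned. The gene lists, cell type markers, intronic signal and YCAY motif tests planned for an annotated genome were not run, and the genes under these regions, including ps itself and MtnA, were not analysed here. Alternatives covered bin and window size, pseudocount, filters, centring, thresholds, a cap on the signal per base, the sequences included, and each library left out. With 1 group, no comparison between groups and no permutation of group labels was possible. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.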

Results

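RNA co-precipitated with ps was profiled in S2R+ cells that carried ps with C-terminal FLAG and HA tags, expressed from the MtnA promoter. The gene ps encodes Pasilla, a KH-domain RNA-binding protein of the NOVA family of splicing regulators. MtnA encodes a metallothionein, and its promoter is switched on by copper. Cells had received 0.35 mM copper sulfate for 24 hours. The data comprised 3 biological replicates of 1 group, with 17916993, 14029729 and 31616295 alignments of 50 bases in replicates 1, 2 and 3. The design implies no contrast between conditions. The questions it allows are where in the genome the co-precipitated RNA came from, how far the replicates agreed, and which regions stood out within the libraries.

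Most of the main chromosome arms carried no signal. Bases with at least 1 alignment made up 21.4%, 23.0% and 26.3% of the arms in replicates 1, 2 and 3, which gave 23.6% ± 2.50 (SD, n = 3). With each library thinned to the depth of replicate 2, the expected coverage was 20.5% in replicate 1, 23.0% in replicate 2 and 21.3% in replicate 3. Bases with at least 5 alignments made up 12.4% ± 1.86 (SD, n = 3) of the arms.

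The main arms, chromosome 4 included, supplied most of the signal, with 84.0% in replicate 1, 81.8% in replicate 2 and 91.9% in replicate 3. Arm 2R held 19.6% ± 0.233 of all signal (SD, n = 3), the smallest SD among the 5 large arms. Its share was lowest in replicate 3, with 19.4% against 19.8% and 19.6%, where the shares of the other large arms were highest. The small SD therefore does not mean that 2R was steady relative to the other arms. X held 18.9% ± 1.80, 3R 18.9% ± 1.95, 3L 15.7% ± 1.32 and 2L 12.1% ± 0.577. Per base, 2R carried 1.76 ± 0.0972 times the signal of 2L (SD, n = 3), with 1.81, 1.82 and 1.65 in replicates 1, 2 and 3. The X chromosome carried 1.22 ± 0.0482 times the mean signal of the 4 large autosomal arms (SD, n = 3), with 1.199, 1.193 and 1.279 in the same order. Both ratios lay above 1 by more than the spread between replicates. Without the 20 highest regions of the main arms, X carried 0.988, 0.985 and 1.19 times the signal of the large autosomal arms, or 1.05 ± 0.115 (SD, n = 3), which did not differ from 1 by more than that spread. The ratio of 2R to 2L was then 1.56 ± 0.0701 (SD, n = 3). Chromosome 4, the small and largely heterochromatic autosome, was covered over 32.3% ± 1.51 of its length (SD, n = 3), against 26.6% ± 2.73 for 2R. Its signal per base relative to the large autosomal arms was 1.03, 0.941 and 0.596 in the 3 replicates, so no difference larger than the spread between replicates was found.

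**Figure D1:**
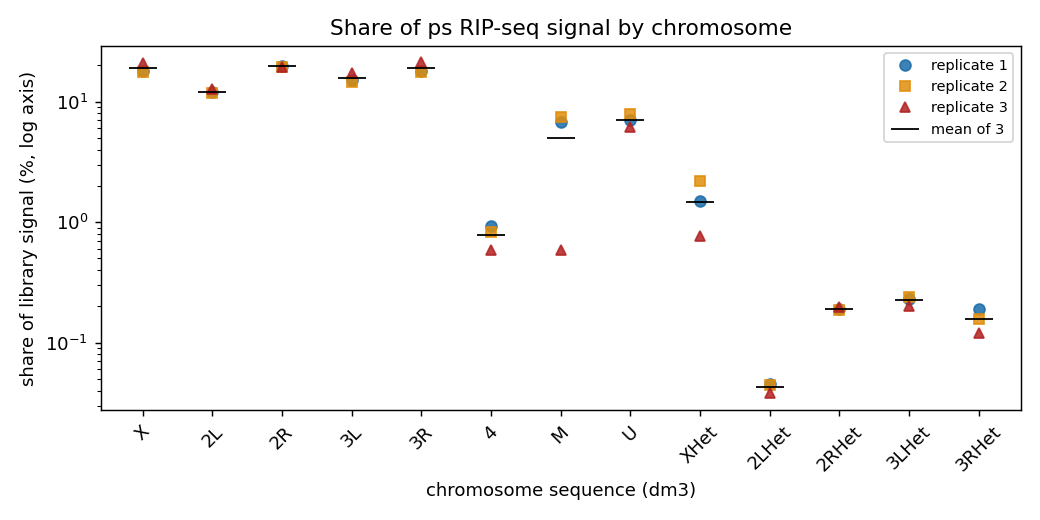
Share of each library's signal (%, log axis) on each dm3 chromosome sequence except YHet, with a point for each of the 3 replicates and a dash for their mean. The points of the 5 large arms lie close together, while replicate 3 lies far below the others on M (0.586% against 6.82% and 7.48%).

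RNA from the mitochondrial chromosome differed most between the libraries. It made up 6.82% of the signal in replicate 1 (95% interval 6.81% to 6.83%), 7.48% in replicate 2 (7.47% to 7.49%) and 0.586% in replicate 3 (0.584% to 0.589%). The mean was 4.96% ± 3.80 (SD, n = 3). The alignments numbered 1222258, 1049358 and 185355. Along the chromosome, signal was uneven and its profile was shared only in part. Replicates 1 and 2 were highest at 11001 to 12000. Replicate 3 was highest at 12001 to 13000, with 95.7 against 584.0 and 587.1 in replicates 1 and 2. In the 12 bins above a signal of 10 in both others, the ratio of replicate 3 to the lower of them ran from 0.00556 to 0.164. In replicate 1 the bin at 11001 to 12000 reached a mean signal of 721.7 and the bin at 2001 to 3000 reached 669.3, while the first 1000 bases had 7.16. The same bins had 840.6, 708.5 and 6.85 in replicate 2, and 21.6, 62.5 and 1.01 in replicate 3. From base 15001 to the end, signal was below 0.1 in every bin and library, and in replicate 3 no alignment lay beyond base 14916.

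**Figure D2:**
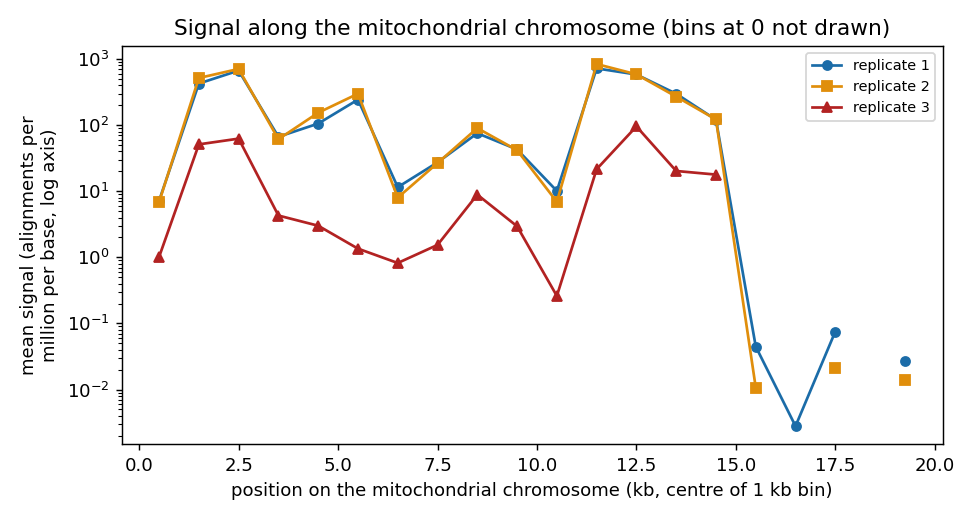
Mean signal (alignments per base, scaled to equal library totals, log axis) in 1 kb bins along the mitochondrial chromosome, with a line for each of the 3 replicates. Bins at 0 are not drawn. Replicate 3 lies below both others in each bin up to base 15000, with the lowest ratio at 5001 to 6000, where it had 1.35 against 243.5 and 299.0.

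The unplaced sequences U held 6.98%, 7.87% and 6.15% of the signal in replicates 1, 2 and 3, and 1.32% ± 0.270 of their length was covered (SD, n = 3). The heterochromatic sequence XHet held 1.497%, 2.184% and 0.761% in replicates 1, 2 and 3. With the signal per base capped at a high percentile of each library, the mean share of U fell from 7.0% to 3.07% and that of XHet from 1.48% to 0.501%. The heterochromatic sequences of the autosomes held little, from 0.0425% ± 0.00402 for 2LHet to 0.224% ± 0.0190 for 3LHet (SD, n = 3). YHet had 26, 23 and 109 alignments in the 3 libraries, or 0.000145%, 0.000164% and 0.000345% of the signal.

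Replicates 1 and 2 resembled each other more than either resembled replicate 3. Across 79719 bins of 1 kb with signal in at least 1 library, Spearman's rho was 0.917 for replicates 1 and 2, 0.884 for replicates 1 and 3 and 0.887 for replicates 2 and 3. Pearson's r of the log2 signal was 0.822, 0.793 and 0.772. Among bins with at least 40 alignments in a pair, 1.62% differed more than 2-fold between replicates 1 and 2 (479 of 29508 bins), where sampling noise alone gave 0.271%. The share was 42.4% between replicates 1 and 3 and 44.1% between replicates 2 and 3, where sampling noise gave 0.334% and 0.447%. A chi-square test of the bin counts gave 6.19 per degree of freedom for replicates 1 and 2, against 221.3 and 208.1 for the pairs with replicate 3. No pair agreed within sampling noise, so no pair was merged. Separate libraries of a single sample can also exceed sampling noise, and the libraries were counted as 3 samples because the labels call them biological replicates. The labels do not say how the cultures were separated, so p-values measure the spread between these libraries.

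**Figure D3:**
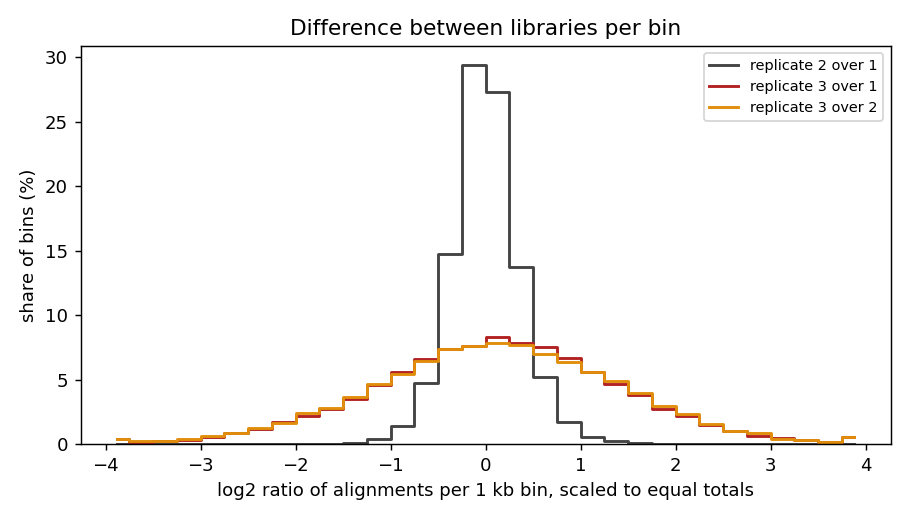
Share of 1 kb bins (%) by the log2 ratio of their alignments in a pair of libraries, scaled to equal totals, for bins with at least 40 alignments in the pair; values beyond the axis are in the end bins. The ratio of replicate 2 to 1 is narrow, and both ratios with replicate 3 are broad, with 42.4% and 44.1% of bins over 2-fold apart.

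Signal was concentrated in few places. The top 1% of bins, 1203 of 120356, held 51.44%, 51.99% and 46.02% of the main-arm signal in replicates 1, 2 and 3, or 49.8% ± 3.303 (SD, n = 3). The median bin with signal in all libraries had a mean signal of 0.102, 0.103 and 0.109.

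The planned test for bins more than 10-fold above the library median called 0 of 79719 bins on the main arms with limma's moderated test and Benjamini-Hochberg adjustment. At an unadjusted p of 0.05, 3268 bins passed, and 4815 bins lay more than 10-fold above the median in every library. Restricted to bins with signal in all 3 libraries, the same test called 1459 of 51304 bins. These calls rose to 2601 without replicate 3, and were 1189 and 1309 without replicates 1 and 2. Of the called bins, 351 lay on 3R, 325 on 2R, 271 on X, 267 on 3L, 234 on 2L and 11 on chromosome 4. As a share of the bins tested on each arm, these were 2.99%, 3.28%, 2.85%, 2.56%, 2.64% and 1.24% in the same order. They formed 873 regions, 520 of them a single bin, and the longest spanned 9 bins on 3L from 569001 to 578000.

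The highest region of the main arms by its lowest library lay on 2R from 20198001 to 20201000. It reached a mean signal of 206.2, 202.7 and 296.3 in replicates 1, 2 and 3, or 235.1 ± 53.0 (SD, n = 3), from 221673, 170658 and 562028 alignments. In its lowest library the region stood at 1969 times that library's median bin. The region on X from 5796001 to 5799000 followed with 281.5 ± 94.8, and its signal peaked at base 5797940. A second region on X, from 9046001 to 9049000, had 227.9 ± 61.7. The region on 3L from 3193001 to 3197000 had 149.4 ± 38.3. Of its 4000 bases, 1525 lay at or above 50% of the peak, the largest number among the 20 regions. They were not 1 unbroken stretch, and the stretch around the peak was 613 bases long, from 3196236 to 3196848. The X region from 11004001 to 11007000 had 83.8 ± 7.39 and the 2R region from 18822001 to 18825000 had 71.0 ± 5.63 (SD, n = 3 for each). The region on 3R from 10558001 to 10560000 varied least, with 43.8, 43.3 and 40.2. Regions were built only from bins that passed the restricted limma test, so their passing is no further support. In these 7 regions the largest adjusted limma p was 0.0384 on 3L at 3193001 and 0.0284 among the others.

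Replicate 3 was the highest library in 9 of the 20 regions and the lowest in the other 11, so that it lay outside the range of replicates 1 and 2 in all 20. In 5 of the 20 the highest library exceeded the lowest more than 2-fold. The region on 3L from 6185001 to 6187000 had 149.3, 151.2 and 35.5 in replicates 1, 2 and 3, a 4.26-fold range. The region on 2R from 8757001 to 8759000 had 128.3, 145.8 and 59.7, and that on 2R from 10245001 to 10248000 had 89.6, 108.4 and 49.3. In the opposite direction, the region on 3R from 14750001 to 14753000 had 59.1, 53.4 and 176.7, and its mean of 96.4 fell to 56.3 without replicate 3. The 2R region from 7781001 to 7783000 had 42.0, 44.1 and 87.5. Together the 20 regions held 11.49%, 11.32% and 10.04% of all signal in the 3 libraries, and 6 of them lay on X, 5 on 2R, 4 each on 3L and 3R, and 1 on 2L.

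**Figure D4:**
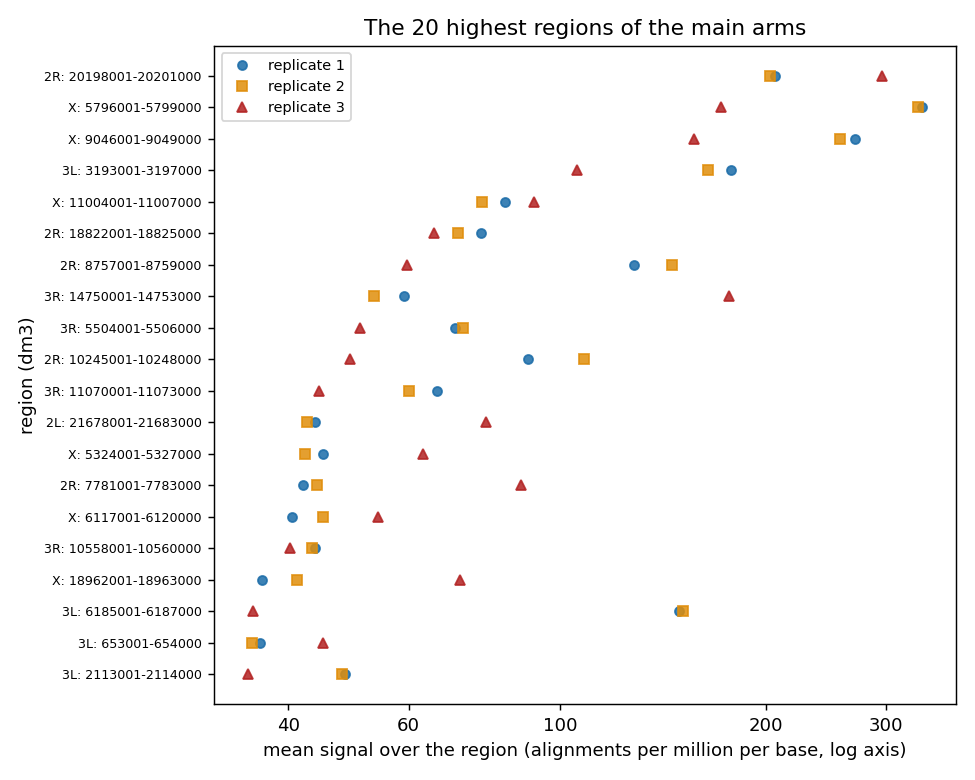
Mean signal (alignments per base, scaled to equal library totals, log axis) in the 3 replicates for the 20 highest regions of the main arms, ordered from the top by their lowest library. Replicate 3 lies outside the range of replicates 1 and 2 in all 20, above it in 9 and below it in 11.

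The 20 regions included 8 others, each with a range below 2-fold. On 3R, 5504001 to 5506000 had 64.4 ± 11.7 and 11070001 to 11073000 had 56.8 ± 11.2. On 2L, 21678001 to 21683000 had 54.7 ± 20.1. On X, 5324001 to 5327000 had 50.1 ± 11.3, 6117001 to 6120000 had 46.5 ± 6.90 and 18962001 to 18963000 had 49.7 ± 18.9. On 3L, the bin from 653001 to 654000 had 38.9 ± 5.26 (SD, n = 3 for each). The last of the 20, a bin on 3L from 2113001 to 2114000 with 43.8 ± 7.66, had a different shape. Only 25.5% of its bases were covered, and 68 bases from 2113368 to 2113435 held 66.7% of its signal.

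Outside the main arms, U and XHet held the highest regions. On U, the region from 5726001 to 5728000 had 653.1, 780.0 and 857.1, and was centred on 71 bases from 5727156 to 5727226 that held 27.8% of it. On XHet, the bin from 191001 to 192000 had 503.1, 799.4 and 222.1, and 50 bases from 191896 to 191945, the length of a read, held 85.3% of it. The highest region of M under the naming rule (merged called bins ranked by their lowest library), from 1001 to 4000, had 387.4, 428.9 and 39.3. A single bin of M, from 12001 to 13000, was higher than this mean in every library, with 584.0, 587.1 and 95.7. The regions named on the other heterochromatic sequences were lower. On 3LHet, 2387001 to 2388000 had 19.5 ± 5.03, and on 3RHet, 788001 to 792000 had 13.9 ± 4.12. On 2LHet, 20001 to 22000 had 5.28 ± 0.174. On 2RHet, 2266001 to 2267000 had 8.11 ± 6.13 (SD, n = 3 for each), which fell to 4.58 without replicate 3. No bin of YHet passed the test.

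Of 122702 windows of 100 bases, 1570 stood more than 4-fold above their own flanks in every library, and 197 passed limma's one-sided moderated test against 4-fold with Benjamini-Hochberg adjustment. These 197 were spread over 3R (48), 2R (46), 2L (40), X (34), 3L (27) and chromosome 4 (2). The largest mean log2 ratio lay on 3L from 20476901 to 20477000, with 394.9, 310.9 and 1063 alignments in replicates 1, 2 and 3 and fewer than 3 in the flanks of each library. It was at least 1053-fold, 829.2-fold and 2835-fold above its flanks in the 3 libraries, at an adjusted limma p of 0.00281. A second summit lay 1 kb away, from 20475901 to 20476000, with 249.0, 192.9 and 907.4 alignments and at least 514.3-fold above its flanks in replicate 2. A pair on 3R, at 5517701 to 5517800 and 5518301 to 5518400, had mean signals of 0.905 ± 0.262 and 1.28 ± 0.0911 (SD, n = 3). The summit on 3R from 14073101 to 14073200 reached 9.28 ± 1.55 and lay 723.6-fold, 559.8-fold and 884.4-fold above its flanks of 400 bases. Its mean log2 ratio fell from 9.47 to 3.47 with flanks of 1000 bases.

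The other 5 named summits had mean signals between 0.480 on 2L at 20457601 to 20457700 and 1.82 on X at 6229701 to 6229800. The others lay on X at 3654101 to 3654200 and 20069501 to 20069600, and on 3R at 3562601 to 3562700. In replicate 3 the summits on X at 3654101 and on 3R at 3562601 rested on 5.94 and 5.98 alignments. The rank by log2 ratio favours windows with nearly empty flanks. All 10 named summits had a footprint of at most 99 bases, and in 7 it was 90 to 99 bases long. The summit on 3R at 14073101 had a footprint of 47 bases, shorter than a read. The call ended without replicate 3 on X at 6229701, 20069501 and 3654101 and on 3R at 3562601, with adjusted limma p of 0.0859, 0.0700, 0.0667 and 0.122. Their mean log2 ratios were then 13.49, 12.67, 9.80 and 8.92, against 12.56, 12.24, 9.60 and 9.35 with all libraries. With flanks of 1000 bases the call ended for 6 of the 10 summits, among them those on 3L at 20475901 and on 3R at 14073101, with adjusted limma p of 0.124 and 1.00. Of these 6, the summit on X at 6229701 still had a log2 ratio of 10.90 and that on X at 3654101 6.66. The ratios of the others fell to between 3.47 and 4.74. In windows of 50 bases the call ended for 3 of the 8 summits that could be tested, on 3R at 5517701 and 5518301 and on X at 20069501.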

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

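No paired analysis was possible because the labels give only 1 group. Outlier tests need at least 4 samples in a group, so none was made. Alternatives for annotated features, gene lists and YCAY motifs were not run, since no dm3 annotation was used here. The restricted test of high-signal bins with single libraries left out, and the ratios between chromosomes without the 20 highest regions, were chosen after seeing the data. The share of M was 4.08% with the signal capped per base, 5.36% without U, and between 3.70% and 7.15% with single libraries left out. The cap moved the share of U to 3.07%, XHet to 0.501%, 2RHet to 0.205%, 2L to 13.0% and 2R to 20.7%. Leaving out U moved 2L to 13.0%, 2R to 21.1% and 2RHet to 0.205% beyond their SD, by the smaller total alone. The shares of X, 3L and 3R rose too, within their SD. Coverage was 20.8% over all chromosomes and 12.4% at 5 or more alignments per base. The lowest rho between libraries was 0.801 in bins of 200 bases, 0.953 in bins of 10 kb, 0.904 in bins with signal in all libraries, and between 0.884 and 0.917 with single libraries left out. The top 1% of bins held 55.3% at 200 bases and 57.7% over all chromosomes. The count of high-signal bins was 0 under the main setting, a larger pseudocount, other centring, bins of 200 bases, a 5-fold threshold and with any library left out. It was 1459 for bins with signal in all libraries, 1189, 1309 and 2601 there without replicates 1, 2 and 3, and 4815 without a model, and on simulated data the main setting called 0% of bins raised 80-fold. Of the summits, 107 were called in windows of 50 bases, 136 with flanks of 1000 bases, 137 at 100 or more alignments, and from 136 to 196 with single libraries left out. The named summits kept their call in 48 of the tests that could be run and lost it in 13, and some of their ratios shrank. With flanks of 1000 bases, each summit of the pair on 3L and of the pair on 3R at 5517701 and 5518301 has the other in its flank. The log2 ratio on 3L then fell from 14.45 to 4.80 at 20476901 and from 10.74 to 3.66 at 20475901, and on 3R from 13.70 to 3.77 and from 9.65 to 4.84. At 20476901 it fell to 4.71 in windows of 50 bases, which leave part of the footprint in the flanks. For the other changes of named summits the cause was not tested. Without replicate 3, the mean signal of the 3R region at 14750001 fell from 96.4 to 56.3 and that of the 2RHet region at 2266001 from 8.11 to 4.58. Counting error was small for chromosome shares other than that of YHet, and large for YHet and for summits with few alignments in a library.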

Other observations

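The tests of the mitochondrial signal, of gap sharing where the other library was deep enough and of summits whose reads all cross 1 base were chosen after the result was seen. The libraries held many short gaps in coverage with abrupt edges. A gap was a stretch of 30 to 300 bases entered by a drop from a depth of at least 20 to 50% or less from 1 base to the next, and left by an equally abrupt rise to at least 20, with no base inside above 50% of the lower edge. On the main arms, 6370, 4930 and 9978 gaps were found in replicates 1, 2 and 3, and 4012 had both ends at the same base in all 3. Their most frequent length was 62 bases in each library, and 71.8% of the shared gaps were 50 to 80 bases long. Inside the shared gaps the median depth was 0.0924%, 0.350% and 0.276% of the flanks. Arm 2R held 46.9 shared gaps per Mb, 3R 35.3, 3L 30, X 27.9, 2L 27.8 and chromosome 4 26.0. A gap could be found only between edges with a depth of at least 20. These densities therefore also depend on how much of an arm was covered that deeply, and were not corrected for it. Of the 20 highest regions, 9 held such gaps. The 3R region at 5504001 had gaps at 5504371 to 5504441 and 5504699 to 5504764, of 71 and 66 bases, and the X region at 9046001 had gaps of 139 and 99 bases.

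A hypothesis for these gaps is that they are introns removed from the precipitated RNA, since short introns of Drosophila cluster near this length. The first test asked for over 50% sharing between any pair of libraries, and the lowest share was 42.2%. That test could not be passed for the pair concerned, because replicate 3 had 9978 gaps and replicate 2 had 4930. Among gaps whose flanks were deep enough in the other library, at least 98.6% had the same ends in every pair. Ends of replicate 1 and replicate 2 gaps matched in 72.4% at the same base and in at most 0.0157% at any offset of 1 to 5 bases. The gaps may be spliced introns. All 3 libraries came from 1 cell line and 1 assembly, so shared ends cannot tell introns from other features fixed in either. Splice-site sequences were not examined here. A low depth inside gaps chosen for a drop in depth does not measure how much unspliced RNA was present.

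The first pattern weighed is the 0.586% of mitochondrial signal in replicate 3 against 6.82% and 7.48%. A filter that removed a single stretch of the chromosome would leave other bins near their level. In the 12 bins above a signal of 10 in both other libraries, the highest ratio of replicate 3 to the lower of the others was 0.164 and the median 0.0728, which argues against it. Dilution by a few abundant sequences would leave the ratio to the other main-arm signal in place, and that ratio was 0.0707 of the lower of the others. A difference in cell fractionation, RNA selection or immunoprecipitation between the replicates stays open, was not tested, and could be technical or biological.

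The second pattern is the closeness of replicates 1 and 2. Depth does not account for it, because with all libraries thinned to the shallowest, their rho still exceeded the higher of the others by 0.0402. Reads of a single library deposited under both numbers would give a chi-square near 1 per degree of freedom, and the value was 6.19, which does not exclude separate libraries of a single culture. A shared day or preparation of replicates 1 and 2, or a wrong label on replicate 3, may lie behind the pattern and was not tested, since the labels give no batch. No biological explanation was tested, as the design has 1 group.

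The third pattern is the shape of the sharp summits, where whole reads stacked at a single position in every library accounted for 1.02% of the 197 summits, which argues against such stacks as the main source. Reads did share start positions in the summit on 3L at 20476901, where replicate 3 had 1063 alignments and the footprint was 98 bases. Whether such reads were amplified copies or separate molecules was not tested and stays open. Duplicated reads in blocks shorter than a read were not tested and stay open too. An exon next to introns can also give a sharp summit, which was not tested, since no exons were assigned. Reads of 50 bases that must all cross a given base span at most 99 bases. Of 35 summits with a footprint of 90 to 99 bases, 27 had at least 95% of the read-equivalents at the peak base. These were 13.7% of all summits but 7 of the 10 named ones. Some summits, some of the named ones among them, may therefore be single alignable positions inside repeated sequence. Whole reads that all cross 1 base cannot give the named summit on 3R at 14073101. Its footprint was 47 bases and its peak depth was 238% of the read-equivalents there. Footprints of at most 99 bases were found in 94 of the 197, and in 25 of these the peak depth exceeded the read-equivalents of the footprint by more than 5%, as blocks shorter than a read would give. Any isolated cluster of unbroken reads that narrow shares a base, so the widths cannot tell these explanations apart, and the alignment settings and genome sequence needed to decide were not used here.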
